A study of Mus musculus with 5 samples.

How the data were processed

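The series holds 5 chromatin immunoprecipitation sequencing (ChIP-seq) libraries from mouse bone marrow derived dendritic cells, 1 per group. Marrow from C57BL/6 females aged 10 weeks was cultured for 7 days with GM-CSF and IL-4 at 10 ng/mL each, and CD11c-positive cells were selected to 95% purity, per the labels. The cells then received diluent or SAHA (vorinostat, a histone deacetylase inhibitor, at a dose labelled 500 nm) for 12 hours. The libraries were STAT3 in diluent, STAT3 in SAHA, H3K4me3 in diluent, H3K4me3 in SAHA and IgG in diluent. The IgG library from diluent cells was the only control used here, for both conditions. Per the labels, chromatin was sheared to fragments of 200 to 500 bp.

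Reads were aligned with BWA to mm9, per the submitters' processing notes, and no version is given in the sources used here. Per the file headers, regions of each single library were called with MACS 1.4.0rc2 without a control, at a p-value limit of 1e-05, with at most 2 duplicate tags per position. The deposited single-library tables give, for each region, its tag count, its fold enrichment (a ratio over the local background) and a score, log10 of p times 10 with the sign changed, per the file headers. The authors' deposited lists against IgG have no header, and they give for each region a MACS score and 1 gene with its distance. How those lists were called is not given in the sources used here beyond their names. The lowest score was 30 in both STAT3 lists and 50 in both H3K4me3 lists, so the limits differed between the marks. Region numbers in the STAT3 lists had gaps, 465 in diluent and 1910 in SAHA, and no such gaps occurred in the H3K4me3 lists. The filter behind the gaps is not given in the sources used here. A score is the region's own value from the authors' lists and served only to describe, rank or filter regions within 1 list. The FastQC tables gave the total reads, read length and duplicate percent of each library.

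Lists were compared by overlap of at least 1 bp with bedtools 2.31.1, and coordinates are 1-based mm9 positions from the files. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only. Chance overlap came from 1000 shuffles of the regions within the span of their chromosome. Fisher's exact test, two-sided, compared the STAT3 lists in their share at H3K4me3 regions, which compares these libraries and not the conditions. With 1 library per group there was no replicate check on any difference between conditions, and no p-value between conditions was computed. Tag ratios at H3K4me3 regions used pairs that overlapped 1 to 1 and had the same ends in the single-library tables. Each library's count was scaled to its filtered tags, and each ratio has an exact conditional binomial interval. Only 2 STAT3 pairs had such counts, so the planned STAT3 ratio was not computed, and STAT3 was compared by overlap alone. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. On simulated counts for the 21342 H3K4me3 regions of the diluent library, 190 of 200 regions raised 2-fold had an interval above 0, and 95.6% of all intervals covered the true ratio. The simulated counts varied by counting error alone over fixed regions, as the interval assumes. They do not test regions called separately in each library or the spread between libraries.

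Gene names followed the files. Symbols that a spreadsheet had turned into dates (6 and 14 in the STAT3 lists and 33 and 42 in the H3K4me3 lists, diluent and SAHA) were restored for March and September. Symbols were matched to RefSeq names of the GRCm38.p6 table, used for names only, and 87.7% of 17024 symbols matched. A gene carried a region when the region lay within 5 kb of a transcription start given in any of the 4 lists, and 14016 protein-coding genes had such a start. The 20 gene lists covered the JAK-STAT pathway, STAT3 and cytokine response targets, regulatory dendritic cell molecules, dendritic cell identity, costimulation and maturation, antigen presentation, inflammatory cytokines and chemokines, TLR and NF-kB signalling, histone acetylation enzymes, H3K4 methylation enzymes, cell cycle inhibitors and HDAC inhibitor responders, apoptosis, housekeeping, and markers of macrophages and monocytes, granulocytes and mast cells, T cells, B cells, NK cells, erythroid cells and non-haematopoietic development. They held 336 genes, of which 289 were scored. Each count was placed among 10000 random lists of the same size. The comparisons, gene lists and most variants were fixed before the data were examined.

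Named genes came from 4 rules: the 10 highest-scoring regions of each list against IgG; the 10 highest-scoring regions found in only 1 condition, per mark; the 5 largest and 5 smallest tag ratios at shared regions; and, per gene list, up to 4 members with a region in only 1 condition and up to 4 with one in both. Predicted and unnamed genes and unplaced contigs were passed over. Median tag ratios per gene list, with random lists matched on mean tags, were added after the data were examined, as was the overlap of the single-library STAT3 lists with H3K4me3. Genes named for these ratios, and those under other observations, fall outside the 4 rules and were picked after their values were seen. Each gene took its paired region nearest the start, and for 12 of 191 listed genes another region nearby scored higher or the region lay on another chromosome; a variant left these genes out.

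A single row of the STAT3 SAHA list, at Ido1, was left out of the counts because its entries contradicted one another. The variants were stricter scores, a reciprocal overlap of 50%, a gap of 1 kb, equal numbers of top regions, removal of regions over IgG regions, other scalings, and windows of 1 kb and 20 kb. Those added later kept the Ido1 row, drew random lists from genes with H3K4me3, divided tags by region width, kept pairs with widths within 10%, or used only starts on the chromosome of the gene, since the files also give symbols to starts elsewhere (64 genes, Gapdh and Blk among those listed).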

Results

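STAT3, a transcription factor activated by cytokine receptors, and H3K4me3, a histone mark of active promoters, were mapped in dendritic cells kept for 12 hours in diluent or in SAHA. The question, as the design states it, was where STAT3 binds in dendritic cells when histone deacetylases are inhibited. Each of the 5 groups had 1 library. Sequencing gave 27920130 reads for STAT3 in diluent, 19504014 for STAT3 in SAHA, 24364949 for H3K4me3 in diluent, 22684718 for H3K4me3 in SAHA and 25882793 for IgG. Filtered tags numbered 25013431, 17810183, 22420200, 21428355 and 18925827 in the same order. Aligned tags made up 77.9% of the IgG reads and at least 97.4% of the reads of each other library. Per the file headers, the STAT3 and IgG libraries came from 1 flow cell and both H3K4me3 libraries from another, so each comparison of SAHA with diluent lay within a flow cell.

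Called against IgG, the SAHA library had more STAT3 regions than the diluent library, and few regions were shared. Called without a control it had fewer, 784 against 844. The IgG library came from diluent cells, and its part in this difference was not tested. Against IgG, 3507 STAT3 regions covering 2.77 Mb were listed in diluent and 8551 covering 5.84 Mb in SAHA, 2.44 times as many from the shallower library. Of the diluent regions, 234 (6.67%, 95% interval 5.87 to 7.55%) overlapped a SAHA region, and shuffled regions overlapped 17.8 times on average. The diluent list was led by a region assigned to Lilrb4, named for an inhibitory receptor of myeloid cells, 26.6 kb from the start that the list gives. Regions assigned to Frmd5, Tnfaip3 (a brake on NF-kB signalling), Lamc1 and Cd53 followed. Regions assigned to Akr1a4, Hlx, Nfkbiz (an inducible regulator of NF-kB target genes), Atp6v1g3 and Ccrl2 completed its top 10, and of these only the one assigned to Hlx overlapped a SAHA region. The SAHA list was led by a region assigned to Axin2, 68.3 kb away, which lay over an IgG region. Next came Arid1b, Clcn7, Zmpste24, Slfn2, Baz1a, Uvrag, Smek2, Aebp2 and Dedd2, and the last pair overlapped diluent regions.

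Within each list, regions found in only 1 condition scored below shared ones: in the authors' deposited table the median was 34.8 against 40.4 in diluent and 35.3 against 40.6 in SAHA. Akap13 completed the 10 highest diluent-only regions. Chl1 and Txndc11 completed the SAHA-only regions, and the regions at Axin2, Chl1 and Txndc11 all overlapped IgG regions. Near misses occurred: the region assigned to Lilrb4 lay 135 bp from a SAHA region and the one at Slfn2 lay 921 bp from a diluent region. The STAT3 gene itself had a STAT3 region in both lists, at chromosome 11, 100800542 to 100801678 in diluent and 100800644 to 100801609 in SAHA (mm9). In SAHA, 1414 regions (16.5%) had their midpoint within 1 kb of the transcription start of the assigned gene, against 418 (11.9%) in diluent.

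**Figure D1:**
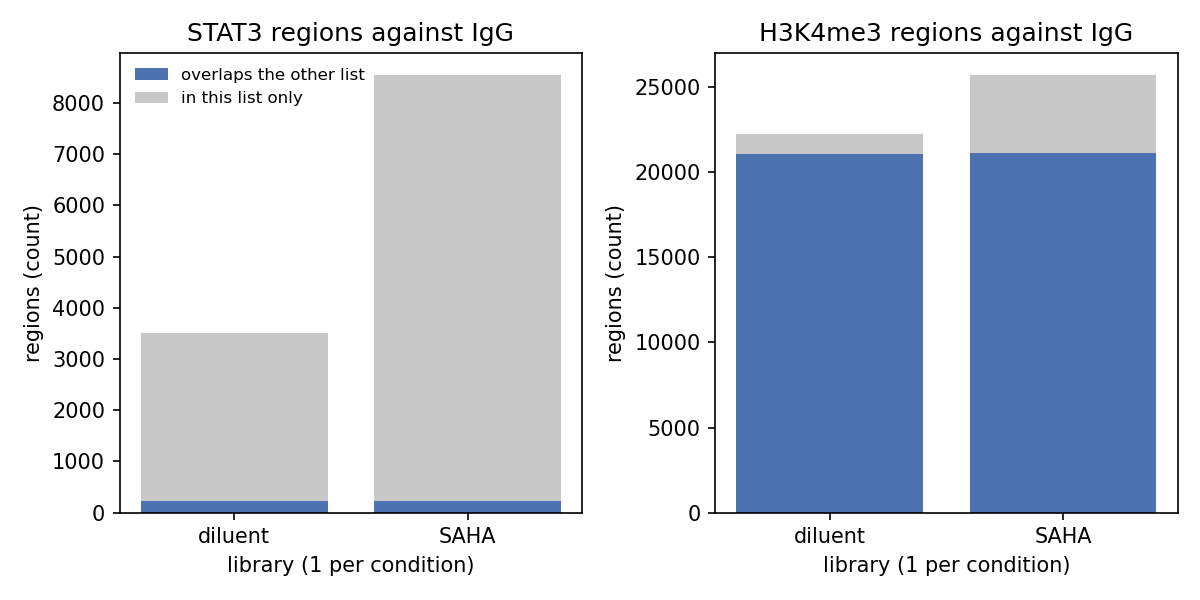
Numbers of STAT3 and H3K4me3 regions against IgG (vertical axes, counts from 0) in the diluent and SAHA libraries, 1 library per bar. Blue marks regions that overlap the other condition's list and grey the rest: 234 of 3507 diluent STAT3 regions were shared, against 21059 of 22255 diluent H3K4me3 regions.

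Members of the fixed gene lists with a STAT3 region differed between the libraries. Among 289 scored genes, 28 had a STAT3 region within 5 kb in diluent and 61 in SAHA, with 8 in both. Of all 14016 scored genes, 894 (6.38%) had one in diluent and 2573 (18.4%) in SAHA, so random lists also had more members in SAHA. Among STAT3 and cytokine response targets, Stat3, Junb and Nfkbiz carried regions in both libraries (at Junb and Nfkbiz different ones, 3374 and 16890 bp apart), and 6 more genes did so in SAHA only, among them Ccnd1, Socs3 (the feedback inhibitor of STAT3 signalling), Bcl6 and Pim1. These 9 of 25 genes in SAHA stood at percentile 98.3 of random lists, and the 3 in diluent at 85.8. Cell cycle inhibitors and HDAC inhibitor responders had 0 of 14 members in diluent and 6 in SAHA (percentile 98.2), among them Cdkn1a, Gadd45b, Cdkn1b and Klf4. Against random lists drawn from genes with H3K4me3, chosen after seeing the data, both SAHA percentiles came below 97.5, at 97.1 for the STAT3 targets. Antigen presentation ran the other way, with 4 of 18 members in diluent (percentile 98.6) and 1 in SAHA (percentile 8.02). H2-DMa carried regions in both (different ones, 8531 bp apart), and the MHC class II gene H2-Ab1, B2m and Psmb8 in diluent only. Regulatory dendritic cell molecules had 4 of 17 members in each library. Il1rn carried regions in both (different ones, 2941 bp apart), Lilrb4a, Arg1 and Il10 in diluent only, and Pdcd1lg2, Lgals9 and Hmox1 in SAHA only. The diluent count stood at percentile 98.9 and the SAHA count at 71.9.

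Macrophage and monocyte markers had 3 of 12 members in diluent (Cd68, Fcgr1 and Cd14, percentile 97.8) and 4 others in SAHA (percentile 89.1), Mertk, Lyz2 and Csf1r among them. Costimulation and maturation genes had Cd44, Cd83 and Slamf7 in diluent and Cd80, Icam1 and Tnfsf9 in SAHA, out of 13 (percentiles 97.2 and 68.0). Inflammatory cytokines and chemokines had Ccl3 in both, Il6 and Ccl5 in diluent only, and Cxcl10, Tnf, Il15 and Csf1 in SAHA only, out of 20 (91.4 and 77.7). The JAK-STAT pathway had Stat3 in both and 5 of 29 members in SAHA only, Socs3, Jak3, Pias1 and Il6ra among them (29.7 and 64.1). TLR and NF-kB signalling had Nfkbie in diluent and Relb and Map3k7 in SAHA, out of 28 (31.1 and 5.80). Histone acetylation enzymes had 0 of 22 in diluent and 4 in SAHA (Kat6b, Hdac7, Hdac3 and Hdac4), at percentiles 11.9 and 51.5. H3K4 methylation enzymes had Setd1b in both, Kdm5c in diluent only and Kmt2b, Ash2l and Kmt2c in SAHA only, out of 14 (85.9 and 82.8). Dendritic cell identity genes had Runx1 in both, Mgl2 in diluent and Spi1 in SAHA, out of 19 (76.8 and 20.7). Apoptosis genes had Bcl2a1a and Cflar in diluent and Bid and Pmaip1 in SAHA, out of 19 (76.8 and 20.7). Housekeeping genes had 0 of 12 in diluent and 4 in SAHA (22.9 and 89.1), Ywhaz and Polr2a among them, and 3 in SAHA when a start given as Gapdh on another chromosome is not counted. Markers of other lineages had Gata3 in diluent and Cd8b1 and Cd4 in SAHA among 9 T cell genes (SAHA percentile 63.8), 2 of 6 B cell genes in SAHA (80.7), Klf1 in SAHA among 3 erythroid genes (73.2), Cebpe in SAHA among 5 granulocyte and mast cell genes (56.9), Foxa2 in SAHA among 6 developmental genes (49.6), and 0 of 4 NK cell genes (22.3). Over the 20 lists and both libraries, 5 of 40 percentiles lay above 97.5, where random lists of all scored genes give 1. Some lists share genes, such as Stat3 and Socs3, so the 40 are not independent. Both of those in SAHA fell below 97.5 among random lists drawn from genes with H3K4me3, a variant chosen after seeing the data. With equal numbers of top regions, 34 listed genes carried a region in SAHA against 28 in diluent. A region near a gene in both libraries was seldom the same region: of the 8 genes, only Stat3 and Runx1 had overlapping regions.

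H3K4me3 regions were mostly the same in both conditions, with additional regions in SAHA. The lists held 22255 regions (44.8 Mb) in diluent and 25723 (52.2 Mb) in SAHA, and 94.6% of the diluent regions (95% interval 94.3 to 94.9%) overlapped a SAHA region. Of the SAHA regions, 4572 (17.8%) overlapped no diluent region, and 9.67% did not with equal numbers of top regions. In the authors' deposited table these SAHA-only regions had a median score of 85.9 and a median length of 743 bp. Shared SAHA regions had 2894 and 1873 bp. The highest-scoring SAHA-only regions were assigned to Cd80 (a costimulatory ligand of T cells), Fgf11, Tnfrsf1b, Ptafr, Itgb7, Irg1 (the enzyme that makes itaconate), Cd274 (PD-L1), Picalm, Fxy and Serpinb1a. The region at Cd80, chromosome 16, 38464810 to 38470146, lay 371 bp from a diluent region and the one at Cd274 lay 1526 bp from one, each beside a region near the gene that both libraries carry. Of these 10 regions, 5 lay within 1 kb of a diluent region, and the region at Fxy overlapped an IgG region. The 1196 diluent-only regions were led by Dnmt3a (a DNA methyltransferase, with 2 regions), Gpd2, Gmpr, Slc27a1, Cdh2, Klc4, Sh3kbp1, Gfra2 and Fgf9. SAHA-only regions lay beyond 5 kb of the assigned start in 72.2% of cases, against 33.1% of shared SAHA regions. The score saturates, with 10123 diluent regions at 3100, so the highest scores in the authors' deposited table do not rank the regions by strength. Regions with the highest scores included Slc29a1, Psd4, Nat15, Pigk, Apol9b, Dgat2, Rnf157, Zfp781, Mapre3 and Rapgef2 in diluent, and Macf1, Ptchd1, Zfp317, Plcd1, Rfc2, Sox4, Rhbdl3, Cdc20, Fam50a and Prss36 in SAHA.

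At shared H3K4me3 regions the tag counts were alike on average, and single regions, called separately in each library, differed in tags by up to 16.3-fold. Over 17704 pairs of regions with counts, the median log2 ratio of SAHA over diluent was -0.01, with quartiles of -0.17 and 0.26. In SAHA, 879 regions were at least 2-fold higher and 179 at least 2-fold lower. By tag sums over the called regions, the largest gain was at a region 56.7 kb from Aim2 (chromosome 1), from 41 to 434 tags, log2 3.47 (95% interval 3.01 to 3.97). Cd28, the T cell costimulatory receptor, went from 19 to 195 tags (log2 3.42, interval 2.74 to 4.19) and Ccr2, the chemokine receptor of inflammatory monocytes, from 145 to 1167 (log2 3.07, interval 2.82 to 3.33). Ufm1 (log2 3.04) and a region assigned to Eea1 from 327 kb (log2 3.01) followed. The deepest losses were a region 33.0 kb from Tlr1, from 342 to 20 tags (log2 -4.03, interval -4.76 to -3.38), Nt5c2 (log2 -2.61), Mbnl2 (log2 -2.44), Mn1 (log2 -2.44) and Isl2 (log2 -2.39). Called width changed with the count: the Cd28 region was 507 bp wide in diluent and 3068 bp in SAHA, and per kb its log2 ratio was 0.83. Per kb the region near Aim2 had 0.82, Ccr2 1.64 and the region near Tlr1 -1.47, so the order by tag sums does not hold per kb. Ufm1 had 1.02 per kb and the region assigned to Eea1 1.32. Nt5c2 had -1.09, Mbnl2 -1.06, Mn1 -0.54 and Isl2 -1.23. Across regions, which are not independent replicates, the ratio of tags and the ratio of widths had a Pearson r of 0.71 and a Spearman rho of 0.57. Counted per kb, 138 regions were at least 2-fold higher and 31 at least 2-fold lower. The total over these pairs was 332 raw tags per kb in diluent and 289 in SAHA, over 36740 and 39890 kb. These totals were not scaled to the filtered tags (22420200 in diluent and 21428355 in SAHA), so part of their difference is depth.

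Of 17 gene lists, 6 had higher H3K4me3 ratios in SAHA than 97.5% of matched random lists, in an analysis added after the data were examined. Regulatory dendritic cell molecules had a median log2 ratio of 0.34 over 14 genes (percentile 99.99), with 10 intervals above 0 and 2 below. Ebi3 (1.58) and Nos2 (1.22) were higher, Havcr2 (-0.81) and Il27 (-0.49) were lower, and Ido1 went from 134 to 168 tags (log2 0.39, interval 0.06 to 0.73, and -0.02 per kb). Costimulation and maturation genes had a median of 0.52 over 8 genes (above every random list), led by Cd70 (0.94), Cd86 (0.93) and Tnfsf9 (0.88). Inflammatory cytokines and chemokines had a median of 0.33 over 13 genes (percentile 99.96), with Ccl17 at 1.24, Il12a at 1.01 and Tnf at -0.24. Antigen presentation genes had a median of 0.22 over 9 genes (percentile 99.95), with 8 of 9 above 0, Ciita at 1.18, and Psmb10 at -0.40. Cell cycle inhibitors and HDAC inhibitor responders had a median of 0.20 over 8 genes (percentile 99.6), from -0.52 at Cdkn2b to 0.64 at Cdkn1c. The JAK-STAT pathway had a median of 0.03 over 22 genes (percentile 98.0, and 88.5 among random lists not matched on tags), led by Cish (0.58). Counted per kb, the median log2 ratio turned negative for costimulation and maturation (-0.10, percentile 81.2, with Tnfsf9 at 0.15) and for the JAK-STAT pathway (-0.08, percentile 98.0). It was near 0 for regulatory dendritic cell molecules (0.01, percentile 95.8) and antigen presentation (0.00, percentile 99.7), 0.07 for inflammatory cytokines and chemokines (98.6) and 0.04 for the cell cycle list (99.7). Single genes were lower per kb too: Ebi3 0.99, Nos2 0.85, Cd86 0.53, Ccl17 0.95, Il12a 0.20, Ciita 0.55 and Cish 0.25.

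**Figure D2:**
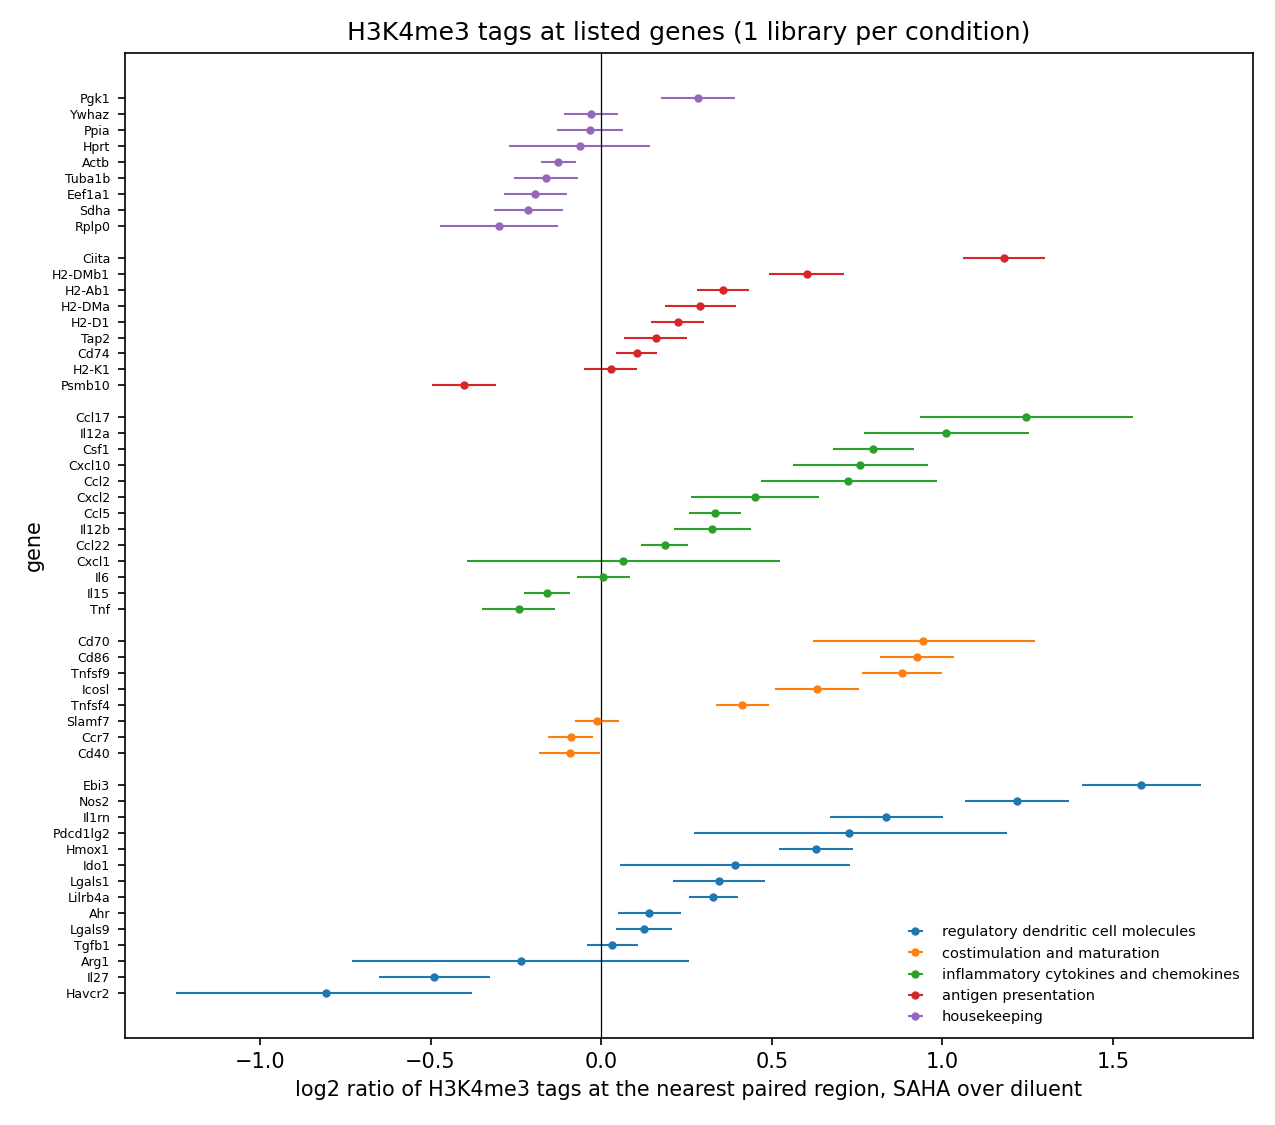
Log2 ratio of depth-scaled H3K4me3 tags, SAHA over diluent (horizontal axis), at the paired region nearest the start of each listed gene (vertical axis), for 5 gene lists in separate colours. Points are single ratios from 1 library per condition and bars are 95% binomial intervals for counting error: regulatory dendritic cell molecules reach 1.58 at Ebi3, and housekeeping genes, without Gapdh, range from -0.30 at Rplp0 to 0.28 at Pgk1.

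The remaining lists lay between percentiles 2.5 and 97.5 of matched random lists, and among lists not matched on tags the erythroid (98.6) and granulocyte and mast cell (98.8) lists lay above. Housekeeping genes had a median log2 ratio of -0.09 (percentile 21.3), H3K4 methylation enzymes -0.11 (28.5), histone acetylation enzymes -0.06 (36.1), TLR and NF-kB signalling -0.05 (45.2), apoptosis -0.05 (51.0, with Fas at 0.84 and -0.01 per kb) and STAT3 and cytokine response targets -0.01 (72.3, with Vegfa at 0.77 and 0.25 per kb). Dendritic cell identity genes had a median of 0.08 (92.3), with Batf3 at 0.32 and Flt3 at -0.56. Macrophage and monocyte genes, with a median of 0.11 (97.1), ranged from Mertk at -0.65 to Ccr2 at 3.07, and T cell genes, with 0.19 (82.2), from Gata3 at -0.88 to Cd28 at 3.42. Granulocyte and mast cell genes (0.45, 88.0) and erythroid genes (0.56, 92.7) were all above 0, over 4 and 3 genes. Without genes whose region was outscored nearby or lay on another chromosome, the median was 0.05 for macrophage and monocyte genes (91.2) and 0.26 for granulocyte and mast cell genes (74.4). Per kb the medians were -0.25 for macrophage and monocyte genes (percentile 7.73), -0.23 for T cell genes (6.34), -0.13 for dendritic cell identity (52.8), 0.24 for granulocyte and mast cell genes (83.1) and 0.37 for erythroid genes (92.0). B cell, NK cell and developmental lists had fewer than 3 genes with a ratio.

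Most listed genes carried H3K4me3 in both libraries. Among 289 scored genes, 268 had an H3K4me3 region in diluent and 267 in SAHA, with 265 in both. Of all 14016 scored genes, 84.5% had one in diluent and 85.5% in SAHA. Only genes whose start the 4 lists give were scored, so listed genes far from every region could drop out. Of the listed genes, 3 of 8 erythroid, 9 of 13 T cell and 6 of 20 developmental genes were scored. All 29 scored JAK-STAT genes, 28 TLR and NF-kB genes, 25 STAT3 and cytokine response targets, 18 antigen presentation genes, 14 cell cycle genes, 13 costimulation genes, 12 housekeeping genes and 3 erythroid genes had a region in both. Both libraries had 21 of 22 histone acetylation enzymes, 13 of 14 H3K4 methylation enzymes, 18 of 19 apoptosis genes, 11 of 12 macrophage and monocyte genes and 4 of 5 granulocyte and mast cell genes. Regions in only 1 library were at Ifnb1, Ido2 and Cd79b in diluent and Mgl2 and Cr2 in SAHA, so that inflammatory cytokines and chemokines had 19 and 18 of 20, regulatory dendritic cell molecules 17 and 16 of 17, and dendritic cell identity 18 and 19 of 19. Some lineage lists had fewer: 5 of 9 T cell genes, 2 of 6 B cell genes, 2 of 4 NK cell genes and 2 of 6 developmental genes in each library. The T cell, B cell and developmental counts lay below percentile 2.5 of random lists, and the JAK-STAT, TLR and NF-kB and STAT3 target counts above 97.5. In the B cell list, Blk carried its region at a start on another chromosome, and without it 1 gene was left in each library.

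STAT3 regions lay at H3K4me3 regions 10.04 times as often as shuffled regions in diluent and 9.63 times in SAHA. In diluent, 874 of 3507 STAT3 regions (24.9%, 95% interval 23.5 to 26.4%) overlapped an H3K4me3 region, against 2.48% after shuffling. In SAHA, 2328 of 8551 did (27.2%, interval 26.3 to 28.2%), against 2.83% after shuffling. In the single-library lists, called without a control, 3.96% of IgG regions overlapped H3K4me3 (2.60% after shuffling), against 18.6% of STAT3 regions in diluent (2.57%) and 21.6% in SAHA (2.95%). Stronger STAT3 regions overlapped more often: at a score of 80 or more in the authors' deposited table, 25 of 38 diluent regions (65.8%) and 70 of 90 SAHA regions (77.8%) did. Shared STAT3 regions did so in 65.8% of cases in diluent and 72.03% in SAHA. The SAHA share was 2.30 percentage points above the diluent share (Fisher's exact test between the lists, p = 0.00964). With the diluent H3K4me3 list for both, that difference over all regions was 0.479 points (p = 0.596, Fisher's exact test). Against each library's own H3K4me3 list, the shares at a score of 50 or more were 44.5% and 54.9%, 10.4 points apart (p = 0.000955, Fisher's exact test). At that score the diluent H3K4me3 list was not used for both, so whether this difference would hold there is not known.

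Without a control, STAT3 enrichment stood near the IgG level. The single-library lists held 606 IgG regions, 844 and 784 STAT3 regions (diluent and SAHA), and 21342 and 23280 H3K4me3 regions. Tags inside called regions made up 0.350% of the IgG tags, 0.321% and 0.394% of the STAT3 tags, and 62.1% and 60.1% of the H3K4me3 tags. IgG regions overlapped 45.4% (95% interval 42.0 to 48.8%) of the diluent STAT3 regions and 51.4% (47.8 to 55.0%) of the SAHA STAT3 regions, against 1.12% and 0.919% of the H3K4me3 regions. Of the 461 diluent STAT3 regions without IgG overlap, 35 (7.59%) overlapped a SAHA STAT3 region.

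At Ido1, which encodes the tryptophan-degrading enzyme indoleamine 2,3-dioxygenase 1, both libraries had an H3K4me3 region, at chromosome 8, 25705436 to 25706784 in diluent and 25705416 to 25707208 in SAHA. The STAT3 diluent list had no region within 5 kb. The authors' deposited table for STAT3 in SAHA gives a region at chromosome 8, 25708146 to 25708770, with a score of 60.6, in a row whose distance, transcript, strand and region number contradict those of the gene, and this row enters no count above. With it, 62 listed genes carried a STAT3 region in SAHA and the regulatory dendritic cell list stood at percentile 86.9.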

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

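Only the permutation test of H3K4me3 regions was set before related values were seen, and the tests on strong STAT3 regions, depth, IgG regions, background level, region widths and markers of other cell types were chosen after the result, or values close to it, had been seen.

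A region with a score of 60.6 stands beside Ido1 in the authors' deposited table for STAT3 in SAHA, in a row the comparisons left out. In that list 8551 of 8552 rows, and every row with a gene in the other 3 lists, give a distance equal to the transcription start minus the region's midpoint to within 1 bp, and this row gives -875 where the Ido1 strand of the other lists would give -976.5. Its transcript identifier belongs to Arl5b on chromosome 2 in the other lists, its strand is + where Ido1 has - there, and it stands between Arl4d and Arl6ip1 in a list ordered by gene name. Its region number, 10442, is also that of a region at Grpr on chromosome X, and it is the only row of the 4 lists out of number order along its chromosome, between 9283 and 9285. Arl5b has 0 regions in the list, and 2 region numbers are unused around the position that a distance of -875 gives at Arl5b. At the Ido1 position 1 number is unused too. In the whole list 1910 numbers are unused, so these gaps do not point to either gene. How the row came to hold these entries was not tested. The single-library STAT3 list of SAHA cells has no region there, but it holds the same ends for only 1.27% of the 8551 regions.

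Few STAT3 regions were shared by the conditions. Chance calls near the score limit as the whole cause would leave the strong regions shared, but 16.4% (95% interval 10.5 to 24.0%) of the 128 regions with a score of 80 or more overlapped the whole other list, against 3.90% of all regions. Whether regions missed at the lower depth of the SAHA library were the whole cause cannot be told. They would be absent from the SAHA list, and that list is the longer, with 8551 regions against 3507. Its length does not decide, because the simulation without binding described below also called more windows at the SAHA depth. Of the SAHA regions, 97.2% (interval 96.9 to 97.6%) were absent from the diluent list. That share does not decide either, because the list sizes leave about 59.0% absent if regions pair 1 to 1, a rule set after that value was seen. Other effects of depth on the calls stay open. A simulation of libraries without binding, at these depths and a p-value limit of 0.001, called 1199 windows in diluent and 1419 in SAHA, so some listed regions may be chance calls. An effect of SAHA on STAT3 binding stays open and untested, since each condition has 1 library.

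Shared STAT3 regions were still more frequent than shuffled ones. A common preference for H3K4me3 regions of like length is argued against as the whole cause of both lists meeting at H3K4me3 regions. Of the diluent H3K4me3 regions, 202 held a STAT3 region of both lists. In 1000 permutations within length deciles the mean was 112 and the highest value 145. Those STAT3 regions need not overlap each other, and regions were matched on length alone. A common preference by strength at equal length stays open. For the lists against IgG, the IgG library common to both calls cannot be told apart as a source. Removing regions over IgG regions left 233 of the 234 shared regions, and so hardly changed the list, a rule set after that value was seen. The single-library lists were called without a control. There, 35 of 461 diluent STAT3 regions without IgG overlap were shared, against 1.61 on average in shuffles (highest 5). This was not set as a test beforehand. Because no control entered those calls, a shared control could not have caused that sharing. The comparison therefore decides nothing for the lists against IgG. Simulated libraries without binding shared 1 window, against 0.364 for independent lists, but that simulation leaves out uneven IgG coverage, so part of the excess may come from the shared control.

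H3K4me3 tags in SAHA were higher at weak shared regions and slightly lower at strong ones, with median log2 ratios of 0.19 in the weakest of 4 equal groups by mean tags and -0.07 in the strongest. Wider called regions as the whole cause would remove the contrast at equal width, but among pairs with widths within 10% the weakest group had a median of 0.0839 (interval 0.0653 to 0.108) and the strongest -0.103 (interval -0.109 to -0.0965). A uniformly higher background stays open: 8.18% (95% interval 7.39 to 9.03%) of the weakest group had an interval below 0 and 27.0% one above, but these intervals cover counting error and not the spread between libraries. A lower share of dendritic cells stays open for the same reason, with 3 of 23 markers of other cell types (Fcgr1, Gata3 and Mertk) below the median of all genes and 13 above. Among those above, the regions used for Elane and Lyz2 were outscored nearby. Selection for CD11c to 95% purity, per the labels, limits cells without CD11c at that step, but not other cells that carry CD11c. An effect of SAHA also stays open.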

How the results depend on the processing

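The variants with the Ido1 row kept, tags per kb, widths within 10%, starts on the chromosome of the gene, genes without a stronger region nearby and other random lists were chosen after seeing the data. No paired analysis was possible because each group has 1 library, and no replicate could be left out. The planned scaling and upper 50% variants of the tag ratio at shared STAT3 regions were not run, as only 2 pairs had counts. Of 68 variants of the main results, 30 stayed within 1.5 times the count or inside the interval, 1 no longer passed its test, 37 moved and 0 reversed. In the lists against IgG, the ratio of SAHA to diluent region numbers stayed close for STAT3 (2.43 to 2.95) and H3K4me3 (1.13 to 1.16). These variants did not include the lists called without a control, where STAT3 regions numbered 784 in SAHA and 844 in diluent. The share of diluent STAT3 regions also in SAHA was 5.78% with both lists at a score of 50 or more, 4.51% at 50% reciprocal overlap, 8.61% with a gap of 1 kb and 4.11% with equal numbers. With only the diluent list at a score of 50 or more, a value added after seeing the data, 56 of 346 diluent regions (16.2%) overlapped the whole SAHA list. For H3K4me3 it was 99.7% in the upper 50% of both lists by score, 96.0% with both at a score of 100 or more, 89.0% at reciprocal overlap, 95.2% with a gap and 90.6% with equal numbers, and the share of SAHA regions absent from diluent was 12.1%, 14.1%, 23.0%, 15.0% and 9.67% in that order. STAT3 regions at H3K4me3 made up 22.9% in diluent and 25.003% in SAHA when 50% of the region had to overlap, 31.5% and 35.1% in the upper 50% by score, and 25.4% in SAHA against the diluent H3K4me3 list, where the difference between the lists fell from 2.30 to 0.479 points (p = 0.596, Fisher's exact test). The cause was not tested. The median H3K4me3 log2 ratio was 0 by construction when centred, 0.0303 scaled to total reads, -0.0657 in the upper 50% by mean tags, -0.0625 at like widths and -0.0690 per kb. Regions at least 2-fold higher and lower numbered 49 and 3 in the upper 50%, 33 and 14 at like widths, and 138 and 31 per kb. Intervals above and below 0 numbered 4281 and 4301, 4398 and 4105 centred, 4895 and 3412 scaled to total reads, 1505 and 3199 in the upper 50%, 1173 and 2782 at like widths, and 2428 and 5902 per kb. Listed genes with a STAT3 region numbered 15 in diluent and 31 in SAHA within 1 kb, 64 and 118 within 20 kb, 34 in SAHA with equal numbers, and 60 in SAHA with starts on the chromosome of the gene only. At reciprocal overlap, 0.553% and 0.399% of the single-library H3K4me3 regions lay over IgG regions. Without genes whose region was outscored nearby or lay on another chromosome, the median log2 tag ratio went from 0.11 to 0.05 for macrophage and monocyte genes, 0.45 to 0.26 for granulocyte and mast cell genes, 0.34 to 0.23 for regulatory dendritic cell molecules, -0.11 to -0.16 for H3K4 methylation enzymes and -0.06 to -0.10 for histone acetylation enzymes, and no percentile crossed 2.5 or 97.5. Of 376 percentile variants of the gene lists, 26 crossed 2.5 or 97.5.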

Other observations

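Beyond the 5 largest H3K4me3 tag ratios, the next in order are named here after their values were seen, with tag sums over regions that also differed in width. A second region at Ciita, the master activator of MHC class II genes, at chromosome 16, 10480119 to 10482154, went from 100 to 740 tags (log2 2.95, 95% interval 2.65 to 3.27, and 1.93 per kb), and H2-Ob, a class II modulator gene, from 65 to 408 (log2 2.72, interval 2.33 to 3.12, and 1.77 per kb). Regions 145 kb and 225 kb from Id2, a transcription factor of dendritic cell development, had log2 ratios of 2.91 and 2.66, and 0.75 and 1.33 per kb. Between these ranked Trfr2 (log2 2.89, and 1.38 per kb) and Nav2 (log2 2.86, and 1.35 per kb), and Clp1 (log2 2.66, and 2.11 per kb) followed. Among falls, Rapgef6 (log2 -2.03, and -1.29 per kb), Lrrc4 (log2 -1.97, and -1.29 per kb) and Epb4.1 (log2 -1.96, and -1.28 per kb) came next. Then came Myoz2 (log2 -1.87, and -1.27 per kb), Baz2a (log2 -1.87, and -1.14 per kb) and Gpr31c (log2 -1.85, and -0.81 per kb). Slamf8, a surface receptor of myeloid cells, went from 295 to 79 (log2 -1.84, and -0.84 per kb). Picked out from the listed genes, Ly6c2, a monocyte marker, went from 298 to 799 tags (log2 1.49, and 1.07 per kb), and Tlr9 from 813 to 459 (log2 -0.76, and -0.41 per kb). These values have no replicate check.

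Of the diluent H3K4me3 regions 848 were wider than 5 kb, and of the SAHA regions 1370. The widest was 14287 bp in diluent and 24538 bp in SAHA. On chromosome Y the single-library lists held 28 IgG regions, 30 and 23 STAT3 regions and 11 and 9 H3K4me3 regions, in cells labelled female, and Xist carried an H3K4me3 region in both libraries. All chromosome Y regions lay between positions 2652045 and 2774640, and none lay elsewhere on that chromosome.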
